A study of Mus musculus with 2 samples.

How the data were processed

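Single-cell suspensions of small intestinal epithelium, isolated with EDTA and dissociated with TrypLE per the labels' protocols, were made into droplet libraries with a 10x Genomics 3-prime kit and sequenced on an Illumina NovaSeq. The authors deposited counts of unique molecular identifiers (UMIs) per gene and barcode, whole numbers and not normalized, for 1 control and 1 doxycycline library. Reads were processed with Cell Ranger 5.0.1 against GRCm38, per the submitters' processing notes. The names of the deposited count tables say that they passed through CellBender, which removes counts attributed to free RNA. Its version and settings, and the annotation release, are not given in the sources used here. Such a correction can lower counts of abundant transcripts in cells that lack them, and its strength may differ between libraries. Each table held 21936 genes, 67 of them under a symbol shared with another gene, and these were kept apart by identifier. Coordinates are those of GENCODE vM21 on GRCm38, matched by Ensembl identifier for 21817 genes.

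Cells were kept with at least 1000 UMIs, at least 500 genes and at most 25% of UMIs from mitochondrial genes. In the control library 12761 of 16808 barcodes exceeded the mitochondrial limit, and in the doxycycline library 4673 of 9548 did. Scrublet, as provided in scanpy 1.11.5, called 0 control and 2 doxycycline cells doublets, and those 2 were removed. At so low a rate the caller has not worked, so doublets remain among the kept cells. Leaving out cells with a score above 0.2 (60 control and 82 doxycycline cells) was an alternative chosen after the data were seen. The kept cells held 57057912 UMIs in the control and 129309875 in the doxycycline library.

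Counts were summed over cells and expressed as CPM, scaled to that sum, so deep cells weigh more. Each ratio is doxycycline over control with an exact conditional binomial 95% interval, each count has an exact Poisson interval and each share an exact (Clopper-Pearson) interval. Where no cell held a UMI, the limit given in its place is 3 cells over the number of cells. None of these covers variation between animals or preparations. A gene was measured at 10 CPM or more in the higher library, and counted as higher or lower at a ratio of at least 2-fold with its interval on that side of 1. Ratios against 0 counts were computed against a floor of 3 counts per library. For each of 28 gene lists, the measured members, the members higher and lower and the median log2 ratio were recorded, with the percentile of that median among 10000 random lists of the same size drawn within 20 expression bins. No test was run and no p-value computed.

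Cells of both libraries were clustered together without integration, on 2000 variable genes, 30 principal components and 15 neighbours. Leiden at resolution 1 gave 22 clusters. The OSKM factors, mitochondrial and ribosomal protein genes and the response lists (pluripotency, injury, YAP/TAZ, prostaglandin, interferon, p53, dissociation stress, ribosome biogenesis, unfolded protein response, cytokines) were left out of the clustering genes. Marker genes of each class were fixed before the data were examined. The naming thresholds were set afterwards. Genes detected in at least 10% of a cluster's cells were ranked by fold over the median cluster with 10 CPM added to both, and a class needed at least 3 markers among the top 50 genes, more than any other class had. At least 66.7% of its markers had to be 2-fold over the median cluster. It also needed 1 marker among the first 5 genes and at least 3 times as many among the first 10 as any other class. Stem and cycling markers were joined as crypt after the clusters were seen. Classes with at least 50 cells per library were compared: enterocyte-like, crypt-like, goblet-like and Paneth-like.

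Named genes followed a rule fixed before the data were examined, as were the filter, the size rule, the lists and most alternatives. Over all kept cells and in the largest class these were the 10 highest and 10 lowest genes with at least 100 CPM. In other classes they were the 3 highest and 3 lowest. Mitochondrial, ribosomal protein and model genes, Xist and Y-linked genes were left out. The OSKM factors, Ptgs1, Ptgs2, Ly6a, Clu, Lgr5 and Olfm4 were always included, with up to 2 extreme members each way of each list. The other genes given per cluster were chosen after their values were seen.

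Alternatives were a looser cell filter (500 UMIs, 250 genes, 50% mitochondrial), a stricter one (2500, 1000, 15%), every deposited barcode, called doublets kept, scaling by the median ratio, the mean over cells of each cell's CPM, no minimum or 50 CPM as minimum, Leiden resolutions of 0.5 and 2, centring within each library, response lists allowed in clustering, and thinning to 2500 UMIs or not at all. Added after the data were seen were the score limit, enterocyte-like cells with at least 10000 UMIs, the goblet-like cluster 14 alone, and naming without conditions on leading genes. Lists of glucocorticoid targets and of stomach, stratified squamous, intestine, ileum, and duodenum and jejunum genes were also written after the data were seen and are used only in the additional observations.

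The size rule was tested on counts simulated for the comparison of all kept cells, with 50 genes changed at each fold size. It marked 0% of genes changed 1.5-fold, 100% of those changed 2.5-fold, 4-fold or 8-fold, and 0% of 7257 unchanged genes. The simulated counts held counting error only, without variation between animals, preparations or cell mix, and did not cover the class comparisons. The 0% is therefore not a rate of false differences between these libraries. The intervals held the true ratio for 95.0% of 7457 genes. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.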

Results

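Epithelial cells of the small intestine were taken from mice that carry the reverse tetracycline transactivator at Rosa26 and a tetracycline-responsive OSKM cassette at Col1A1, so that doxycycline switches on the reprogramming factors Oct4 (Pou5f1), Sox2, Klf4 and c-Myc (Myc). Single-cell transcriptomes were collected for 1 doxycycline library (0.15 mg/ml doxycycline with 5% sucrose, 4 days) and 1 control library (5% sucrose alone, 4 days). The comparison asks how the epithelium of an animal with induced OSKM differs from that of a control. The labels describe the doxycycline library as 1 mouse, and do not say how many animals gave the control library. They name the tissue as small intestine, without saying which parts of it were taken for either library. The control library held 16808 barcodes with 96302578 UMIs (median 2379.5 per barcode), and the doxycycline library held 9548 barcodes with 153856539 UMIs (median 7925). After the cell filter, 3763 control barcodes (22.4%, 21.8 to 23.0) and 4850 doxycycline barcodes (50.8%, 49.8 to 51.8) were kept, with median depths of 4746 and 24356.5 UMIs. Mitochondrial transcripts made up a median of 51.0% of UMIs per deposited barcode in the control and 24.4% in the doxycycline library. With 1 library per group there are no replicates and no tests. Every interval is a 95% interval that covers counting error only, and each ratio compares these libraries and has no replicate check.

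Pou5f1, the Oct4 gene, was higher in the doxycycline library, with a log2 ratio of 3.46 (3.10 to 3.84), at 1.14 CPM from 65 UMIs in the control and 12.5 CPM from 1616 UMIs in the doxycycline library. Sox2 had 1 UMI in the control and 254 in the doxycycline library, a log2 ratio of 6.81 (4.32 to 12.12), although it stayed below 10 CPM in both. The other 2 factors did not pass the size rule over all kept cells, with log2 ratios of -0.34 for Klf4 (-0.37 to -0.31) and 0.40 for Myc (0.29 to 0.51). In enterocyte-like cells thinned to 2500 UMIs, 0 of 825 control cells held a Myc UMI, which allows up to 0.364%. Of the doxycycline cells, 44 of 2274 did (1.93%, 1.41 to 2.59). Crypt-like shares for Myc were 7.23% in the control (5.24 to 9.68) and 11.9% in the doxycycline library (9.62 to 14.4). Those intervals overlapped, as did the goblet-like and Paneth-like ones. In the GRCm38 build Pou5f1 (ENSMUSG00000024406) lies on chromosome 17 from 35506018 to 35510772 and Sox2 (ENSMUSG00000074637) on chromosome 3 from 34650405 to 34652461. Klf4 (ENSMUSG00000003032) lies on chromosome 4 from 55527143 to 55532466 and Myc (ENSMUSG00000022346) on chromosome 15 from 61985391 to 61990374. The counts do not separate transcripts of the cassette from those of these genes, and the sources used here do not say whether the reference used for counting takes up cassette transcripts, so these ratios may include all, part or none of them. With every cell weighing the same, the log2 ratio was 4.32 for Pou5f1, 5.35 for Sox2 and 1.05 for Myc, past 2-fold, and over every deposited barcode Pou5f1 had 4.16. Of 18 pluripotency genes such as Nanog and Zfp42, 2 reached 10 CPM in either library (Klf2 and Tfcp2l1) and neither passed the size rule (median log2 -0.021). Within classes they did, with both higher in crypt-like cells (Klf2 1.16, Tfcp2l1 1.64), Klf2 higher in enterocyte-like cells (1.51) and lower in goblet-like cells (-1.95), and Tfcp2l1 higher in Paneth-like cells (1.09). With every cell weighing the same, Klf2 in crypt-like cells had 0.57 (0.62 under a looser filter) and Tfcp2l1 in Paneth-like cells -0.058 (0.56 with median scaling), and in the goblet-like cluster 14 alone Klf2 had -0.97.

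With every kept cell thinned to 1000 UMIs, 2.68% of the doxycycline cells (2.24 to 3.17) and 0.159% of the control cells (0.0585 to 0.347) held a Pou5f1 UMI. For Ly6a, a surface protein known from regenerating and fetal gut epithelium, the shares were 6.33% (5.66 to 7.05) and 0.957% (0.671 to 1.32). Cells with a UMI of the stem cell receptor Lgr5 made up 0.103% of the doxycycline cells (0.0335 to 0.240) and 0.558% of the control cells (0.346 to 0.852). Without thinning, at median depths of 24356.5 and 4746 UMIs, the doxycycline and control shares were 17.3% and 1.65% for Pou5f1, 19.7% and 5.05% for Ly6a, and 2.99% and 5.66% for Lgr5. As background classes, thinned enterocyte-like cells held an Lgr5 UMI in 0 of 1251 control and 0 of 2322 doxycycline cells, which allows up to 0.240% and 0.129%. Thinned Paneth-like cells held a Pou5f1 or Ly6a UMI in 0 of 85 cells of either library, which allows up to 3.53%. That limit lies below the doxycycline share for Ly6a but above the one for Pou5f1, so 85 cells could not set the Pou5f1 share apart. Paneth-like cells of the doxycycline library may also express the cassette, so they need not lack Pou5f1. Between the libraries, the counting intervals of the Pou5f1 share (2.24 to 3.17 and 0.0585 to 0.347) lie apart. Without thinning, Paneth-like cells held a Pou5f1 UMI in 1 of 85 control (1.18%, 0.0298 to 6.38) and 6 of 85 doxycycline cells (7.06%, 2.63 to 14.7), and a Ly6a UMI in 0 of 85 and 6 of 85. Enterocyte-like cells then held an Lgr5 UMI in 0 of 1251 control and 1 of 2322 doxycycline cells (0.0431%). The median unthinned depths of those classes, control then doxycycline, were 3064 and 25150 UMIs for enterocyte-like and 49853 and 72811 UMIs for Paneth-like cells.

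Over all kept cells, the doxycycline library had higher levels of genes of injured and fetal-like epithelium, of villus tip genes and of the prostaglandin synthase Ptgs1, and lower levels of MHC class II and interferon response genes and of the stem cell genes Lgr5 and Olfm4. Ly6a was 11.3-fold higher (10.4 to 12.4; 8.90 and 101 CPM) and Clu, a gene of revival stem cells, 13.8-fold higher (10.8 to 18.0). Ptgs1, which encodes cyclooxygenase 1, was 14.2-fold higher (11.1 to 18.4), while Ptgs2 (cyclooxygenase 2) had 7 and 105 UMIs, a log2 ratio of 2.73 (1.63 to 4.08) at levels under 1 CPM. Without thinning, 20 of the 23 control cells with a Ptgs1 UMI were tuft-like. In the doxycycline library, which held 1 tuft-like cell, 307 of 567 cells with one were in the unnamed cluster 7. The Ptgs1 ratio thus compares mostly different kinds of cells. Lgr5 was lower, with a log2 ratio of -2.38 (-2.58 to -2.18), and Olfm4, another stem cell marker, 3.90-fold lower (3.84 to 3.96). Ptgs1 (ENSMUSG00000047250) lies on chromosome 2 from 36230426 to 36252272, Ly6a (ENSMUSG00000075602) on chromosome 15 from 74994877 to 74998031 and Lgr5 (ENSMUSG00000020140) on chromosome 10 from 115450311 to 115587780. By size alone (at least 2-fold, counting interval on that side of 1, at least 10 CPM in the higher library), 385 of 8070 measured genes were higher and 674 lower in the doxycycline library. With every cell weighing the same, 1433 were lower, and the log2 ratio was 4.67 for Clu, 2.80 for Ptgs1 and 1.98 for Ptgs2. Over every deposited barcode these were 4.47, 4.59 and 3.41.

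Gkn1, which encodes a gastrokine of the stomach mucosa, had the highest ratio, with 0 UMIs in the control and 19703 in the doxycycline library, at least 2898-fold higher against a floor of 3 counts for the control library. Fam25c, also at 0 in the control, was at least 2339-fold higher. Ly6g6c (log2 10.82), Tm4sf1 (10.57), Mal (7.66), Ada (6.24), Saa1 (6.03), Sprr2a3 (5.05), Fkbp5 (4.46) and Pmp22 (4.35) completed the 10 highest genes with at least 100 CPM. Of the 10 lowest at that level, Gzmb (-8.79), Gzma (-7.01), Cd7 (-6.67), Rgs1 (-6.17) and Ccl5 (-5.81) are lymphocyte genes, and Gcg, the lowest of the 10, and Cck (-6.61) encode enteroendocrine hormones. Ccl6 (-5.25) and Clca1 (-4.32) were goblet markers here, and Apol10a had -4.81. Beside these values, T cell or intraepithelial lymphocyte-like cells were 8.72% of the control and 0.474% of the doxycycline cells, goblet-like cells 17.9% and 3.13%, and enteroendocrine-like cells 1.22% and 0.392%. These shares alone do not account for all the ratios. Cck fell by more than the enteroendocrine-like share, and Ccl6 was also lower within goblet-like cells. In the doxycycline library Gcg was at 2.09 CPM in the unnamed cluster 4 against 0.0252 in the other cells, both under 10 CPM. That ratio (82.9, 24.7 to 434) rests on few UMIs and does not say how many cells held them.

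Among the gene lists, 14 of 26 measured injury-associated and fetal-like genes were higher and 5 lower, with a median log2 ratio of 1.10 that exceeded 100% of 10000 random lists matched on expression. Anxa1 had the highest ratio (8.08) and Vim, which leukocytes express strongly, the lowest (-5.18). Villus tip genes were higher in 6 of 9 (median 2.05), led by Ada and by Apoa4 (3.40), an apolipoprotein of chylomicrons. Prostaglandin genes were higher in 3 of 7 (median 0.75), including Hpgd (2.03), the enzyme that degrades prostaglandins. Lipid absorption genes were higher in 7 of 19 (median 0.33), glycolysis genes in 2 of 14 (median 0.68; Slc16a3 1.96) and brush border cytoskeleton genes in 2 of 12 (median 0.45; Espn 1.58). Nutrient and bile acid transporters held 4 higher and 1 lower of 16 (median 0.23), the lower one being Fabp6 (-3.32), the bile acid binding protein of the ileum. Transporter and enzyme ratios also depend on the parts of the small intestine taken, which the labels do not give.

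All 6 measured MHC class II genes were lower in the doxycycline library (median -3.29), with Cd74, the invariant chain, 10.4-fold lower (10.1 to 10.6). Lymphocyte-like cells, 8.72% of the control and 0.474% of the doxycycline cells, held Cd74 at 93.8 CPM in the control. Interferon response genes were lower in 11 of 13 (median -1.62; Isg15 -2.61). Antimicrobial genes divided, with 2 higher and 7 lower of 13 (median -1.45): Saa1 and S100a9 were higher, Duox2 (-3.39) and Reg3a (-2.56) lower. Stem cell genes were lower in 4 of 12 (median -0.92), and Wnt targets in 3 of 10 with 1 higher, Sp5 (median -0.84; Ccnd1 -1.80, Sp5 1.44). S phase genes were lower in 2 of 20 (median -0.58) and G2 and M phase genes in 3 of 20 (median -0.51; Mki67 -1.07). Notch and secretory fate genes were lower in 4 of 8 (median -1.24; Spdef -2.82), and unfolded protein response genes in 4 of 11 (median -0.44; Pdia4 -1.68). Brush border digestive enzymes divided into 4 higher and 5 lower of 15 (median -0.32), with sucrase-isomaltase (Sis) at 1.93 and lactase (Lct) at -2.28.

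The remaining lists held few genes past the size rule. YAP/TAZ targets had 2 higher and 1 lower of 7 (median 0.26), p53 targets 2 and 0 of 11 (median 0.12; Cdkn1a 1.55), and senescence genes 1 and 0 of 4 (median -0.16), the higher one again Cdkn1a. Inflammatory cytokines and chemokines had 3 higher, such as Il33 (2.05), and 1 lower, Tnfaip3 (-2.12), of 7 (median 0.010). Intestinal identity regulators had 1 higher, Pparg (2.11), of 16 (median 0.29), and villus bottom genes 1 higher and 2 lower of 8 (median -0.37). Dissociation stress genes had 1 lower, Hsph1, of 17 (median -0.072). None of 19 ribosome biogenesis genes (median -0.12) or of 14 chromatin and DNA methylation genes (median -0.41) passed the size rule.

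**Figure D1:**
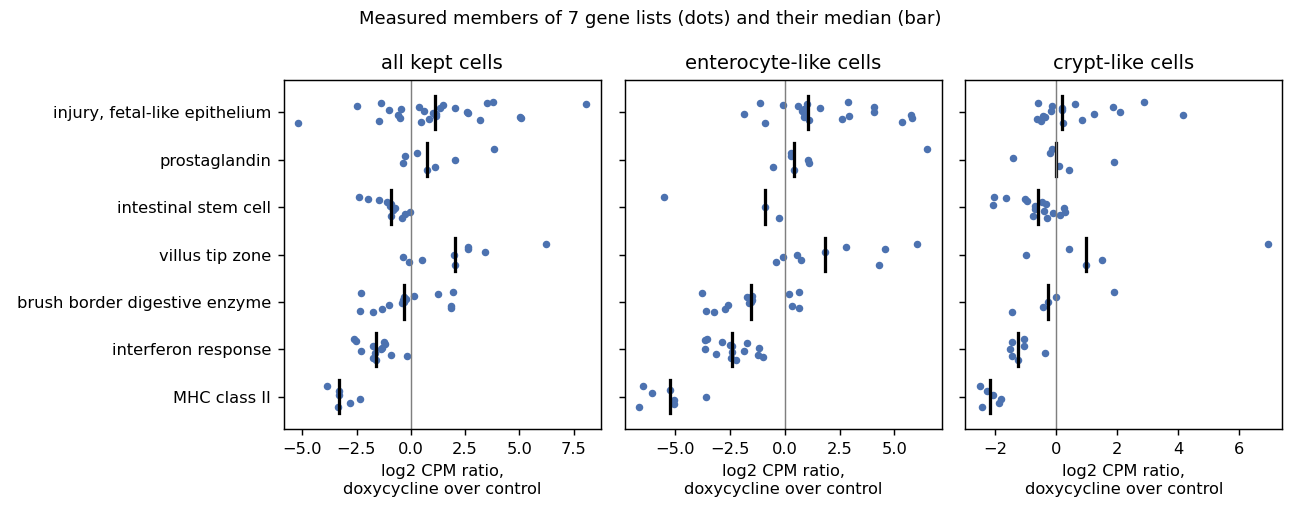
Log2 CPM ratio, doxycycline over control library, of the measured members (dots) of 7 gene lists and their median (bar), over all kept cells and within enterocyte-like and crypt-like cells, with a member at 0 UMIs in one library drawn at its bound against 3 counts. The MHC class II members lie left of 0 in all 3 panels.

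Goblet-like, lymphocyte-like, enteroendocrine-like and tuft-like cells formed smaller shares of the doxycycline library, and enterocyte-like cells a larger one at the main settings. Goblet-like cells were 17.9% of the control (16.7 to 19.2; 674 cells) and 3.13% of the doxycycline cells (2.66 to 3.66; 152 cells). Enterocyte-like cells were 33.2% (31.7 to 34.8) and 47.9% (46.5 to 49.3), and crypt-like cells, which join stem and cycling cells, 16.0% (14.9 to 17.2) and 15.3% (14.3 to 16.3). T cell or intraepithelial lymphocyte-like cells were 8.72% (7.83 to 9.66) and 0.474% (0.301 to 0.711), and Paneth-like cells 2.26% (1.81 to 2.79) and 1.75% (1.40 to 2.16). Enteroendocrine-like cells were 1.22% (0.896 to 1.63) and 0.392% (0.236 to 0.611), and tuft-like cells 0.638% (0.409 to 0.948) and 0.0206% (0.000522 to 0.115). Clusters that took no name held 752 of the 3763 control cells and 31.1% of the doxycycline cells. The depth gap and the mitochondrial filter, which removed more of the control barcodes, can set these shares. Enterocyte-like cells were 19.7% of the control and 49.7% of the doxycycline cells under a stricter filter, 37.8% and 42.0% under a looser one, and 46.4% and 48.3% at a Leiden resolution of 0.5, where their counting intervals overlapped. Under the stricter filter Paneth-like cells were 4.29% and lymphocyte-like cells 15.9% of the control, and under the looser one 1.33% and 5.17%, with goblet-like cells at 8.67% of the control and crypt-like cells at 10.1% of the doxycycline library. Without conditions on leading genes, set after the clusters were seen, goblet-like cells were 16.2% of the doxycycline library, because cluster 4 then took that name, and Paneth-like cells 7.60% of the control, because cluster 15 did.

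**Figure D2:**
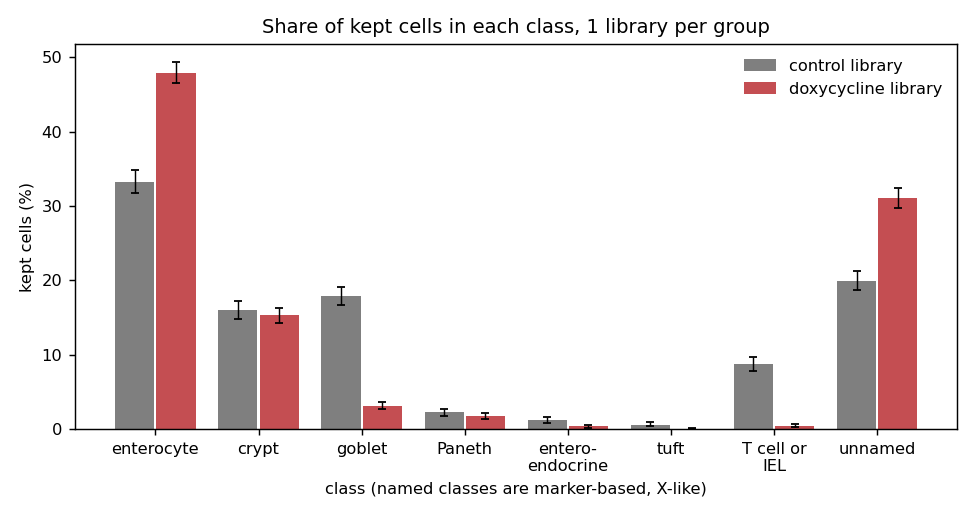
Share of kept cells (%) in each class in the control library (grey, 3763 cells) and the doxycycline library (red, 4850 cells), with exact binomial 95% intervals for counting error as lines. Goblet-like cells were 17.9% of the control and 3.13% of the doxycycline cells.

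Pou5f1, Ly6a, Clu and Ptgs1 were unevenly spread over the doxycycline library and, among clusters with at least 50 of its cells, highest in cluster 7, which held 540 doxycycline cells and 0 control cells. None of these genes had been used for clustering. In cluster 7, Pou5f1 was at 51.7 CPM against 8.88 in the other doxycycline cells, Ly6a at 746 against 41.5, Clu at 122 against 6.03, Ptgs1 at 124 against 6.55 and Ptgs2 at 9.27 against 0.0338. Injury-associated and fetal-like genes had 19 of 29 members higher and 3 lower (median log2 1.53) over the other doxycycline cells, with Anxa1 at 439.8 against 6.22 CPM, and YAP/TAZ targets had 8 of 11 members higher and 1 lower (median log2 1.88). Dissociation stress genes moved with them, with 5 of 17 members higher and 1 lower (median log2 0.63), led by Hspa1a and Hspa1b. The genes that define the cluster were led by Ly6g6c, Gkn1, Tm4sf1, Mal and Fam25c. Cluster 4 (635 doxycycline cells, 1 control cell) came next for Pou5f1 (40.8 CPM), Ly6a (304) and Clu (54.2) but not for Ptgs1, at 12.2 against 16.8 in the other doxycycline cells. Its leading genes joined Fam25c and Mal with the goblet genes Fcgbp, Agr2 and Spink4. Cluster 12 (296 doxycycline cells, 1 control cell), led by Dmbt1, Cdca3, Edn1 and Fkbp5, held Pou5f1 at 7.71 and Ly6a at 18.3 CPM. A cluster made mostly of 1 library may be that library and not a cell type. The unnamed clusters of mostly control cells were 6 (534 control and 17 doxycycline cells) and 15 (201 and 16), and cluster 21 held 15 and 2 cells.

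**Figure D3:**
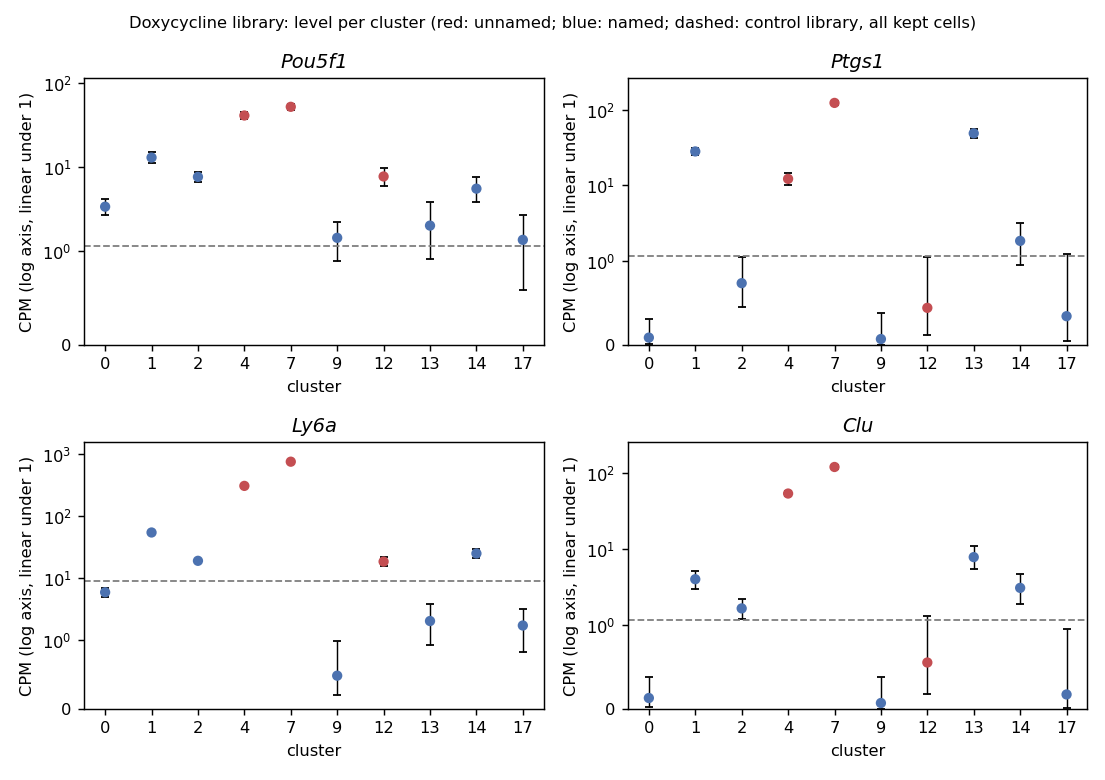
CPM (log axis, linear under 1) of Pou5f1, Ptgs1, Ly6a and Clu in each cluster with at least 50 doxycycline cells, in that library, with unnamed clusters in red, named clusters in blue, 95% Poisson intervals for counting error as lines and the control library over all kept cells as a dashed line. Each of the 4 genes is highest in cluster 7, with Ly6a at 746 CPM.

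Enterocyte-like cells of the doxycycline library had lower MHC class II, interferon response and digestive enzyme genes and higher villus tip, injury-associated and ribosome biogenesis genes than those of the control library. The class came mainly from clusters 5, 10 and 16 in the control and clusters 0, 1, 9 and 13 in the doxycycline library, with median depths of 3064 and 25150 UMIs. All 7 MHC class II genes were lower (median log2 -5.22), with H2-Aa at 257 CPM in the control and 2.92 in the doxycycline library. Their transactivator Ciita had a log2 ratio of -6.64 (-7.62 to -5.80). Interferon response genes were lower in 14 of 15 (median -2.41; Ifit1 -3.63, Oasl2 -3.62). Digestive enzymes were lower in 11 of 15 (median -1.53), from Lct (-3.78) to Sis, which did not pass the size rule at 0.65. Transporters were lower in 6 and higher in 1 of 17, with the ileum gene Fabp6 at 4124 and 247 CPM. A difference in the parts of the intestine taken is therefore not ruled out for these genes, nor for the others compared. Lipid absorption genes were lower in 5, such as Fabp2 (-1.75), and higher in 2, Apoa4 (1.85) and Dgat2, of 19.

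Villus tip genes were higher in 5 of 9 (median 1.85), with adenosine deaminase (Ada) at 12.6 and 813 CPM. Injury-associated genes were higher in 11 and lower in 2 of 20 (median 1.06), and S100a6, a calcium-binding protein, was 53.9-fold higher (47.7 to 61.1). Ribosome biogenesis genes were higher in 7 of 13 (median 1.19; Npm1 2.18, Fbl 3.06), although Fbl turned to -0.63 at a Leiden resolution of 0.5. Ptgs1 rested on 1 control UMI and had a log2 ratio of 6.50 (4.01 to 11.80), Ly6a had 2.88 (2.21 to 3.64) and Pou5f1 2.60 at levels under 10 CPM (1.54 to 3.93). The 10 highest genes with at least 100 CPM were Fkbp5 (6.89), Ada, S100a6, Tm4sf4, Tubb2a, Ly6m, Enpp3, Rbm3, Tspan1 and Ptma (3.60). Fam151a, H2-Aa, Plb1, H2-Eb1, Ifit1bl1, Apol10a and Sectm1b were among the 10 lowest at that level, beside the goblet genes Zg16 (-5.50) and Muc2 (-5.23) and the globin gene Hbb-bs, at 156 CPM in the control and 0 UMIs in the doxycycline library, at least 2916-fold lower. In all, 603 of 7176 measured genes were higher and 1424 lower. Genes above 10 CPM in both libraries had a median log2 ratio of -0.20, and ratios taken relative to that shift gave 816 higher and 1036 lower, so 44.1% of the marked genes in place of 29.7% were higher. In the 181 control and 1849 doxycycline cells with at least 10000 UMIs, 735 genes were lower. With all cells weighing the same 2322 were lower, and under the looser cell filter 967 were higher. At that resolution 319 were higher, and Ptma turned to -0.48.

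Crypt-like cells of the doxycycline library had lower Lgr5, Olfm4 and MHC class II levels and higher S100a6, Fkbp5 and metallothionein levels. Lgr5 was 4.10-fold lower (3.47 to 4.86; 28.8 and 7.02 CPM) and Olfm4 3.11-fold lower (3.06 to 3.16), both being among the markers that name the class. Stem cell genes were lower in 4 of 16 (median -0.58), while Soat1 (0.28) and Igfbp4 (0.26) had the highest ratios. Cycling genes lay closer together, with 1 of 23 S phase genes lower (Cdc6 -1.31) and 0 of 20 G2 and M phase genes past the size rule. All 6 MHC class II genes (median -2.16) and 6 of 7 interferon response genes (median -1.23) were lower. Injury-associated genes were higher in 5 of 17 (median 0.20), with S100a6 18.0-fold (15.8 to 20.5) and Ly6a 7.27-fold (5.29 to 10.3) higher. The p53 targets Trp53inp1 (2.64) and Cdkn1a (1.81), the cell cycle inhibitor p21, were the 2 higher of 9. Dissociation stress genes had 2 higher, Fos (1.51) and Zfp36 (1.05), and 1 lower, Hsph1 (-2.07), of 17 (median 0.56). The 3 highest genes with at least 100 CPM were S100a6, Fkbp5 (3.92) and Mt2 (3.09), and the 3 lowest Fabp6 (-4.17), Clca3b (-2.65) and Cd74 (-2.41). Of 8010 measured genes, 157 were higher and 289 lower, or 516 lower with every cell weighing the same. Cluster 3 held most crypt-like cells of the control (median 21975 UMIs) and cluster 2 those of the doxycycline library (35563 UMIs).

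Goblet-like cells of the doxycycline library had higher levels of Fkbp5, of the fat absorption genes Fabp1 and Apoa4, of Lcn2 (4.73) and of Saa1 (3.97), and lower MHC class II and interferon response genes. Antimicrobial genes as a list, which holds Lcn2 and Saa1, were higher in 3 and lower in 6 of 14 (median -0.68). Among genes with at least 100 CPM, Fkbp5 (4.85), the alcohol dehydrogenase gene Adh6a (4.10) and Apoa4 (3.22) were highest. The lowest of these were Defa39 (-7.72), Ccl6 (-6.42) and Itln1 (-6.21), and Lyz1 had -3.44. Defa39 and Lyz1 are Paneth cell products. Itln1, one of the Paneth markers, was also among the 10 leading genes of the goblet-like clusters 8 and 18. MHC class II genes were lower in 6 of 6 (median -1.86), interferon response genes in 13 of 15 (median -1.45) and unfolded protein response genes in 4 of 11 (median -0.79). Lipid absorption genes were higher in 5 of 17 (median 0.73; Fabp1 2.99). Beside them, digestive enzyme genes of enterocytes were higher in 4 and lower in 3 of 11, and genes of cycling crypt cells had positive medians, 0.56 for S phase with 3 of 21 higher and 0.66 for G2 and M phase with 1 of 20. Of 20 ribosome biogenesis genes 0 were higher, with a median of 0.55, and this median and those of both cycling lists exceeded 100% of random lists. Of 8005 measured genes, 327 were higher and 411 lower, or 228 and 511 relative to the median log2 ratio of 0.11, so that 30.9% in place of 44.3% of the marked genes were higher. They were 726 and 680 at a Leiden resolution of 2 and 632 and 681 with every cell weighing the same, and 560 were higher without conditions on leading genes. Median depths were 13139 UMIs in the control and 40375.5 in the doxycycline library. Most control goblet-like cells came from cluster 8, and cluster 14 held 106 control and 113 doxycycline cells. The median Scrublet doublet score of its doxycycline cells was 0.0758, against 0.0243 to 0.0430 in the other clusters with at least 50 doxycycline cells, apart from cluster 17. In cluster 14 alone Ifit1 turned from -3.57 to 1.09, the G2 and M phase gene Ccnb1 from 1.27 to -0.037 and the digestive enzyme gene Ggt1 from -1.77 to 2.09.

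Paneth-like cells, the only compared class held by 1 cluster (17; 85 cells per library), had higher Fabp1 and lower MHC class II genes in the doxycycline library. Fabp1 (8.66, 6.80 to 11.70), the metallothionein gene Mt2 (7.45) and Apoa4 (7.26) were highest among genes with at least 100 CPM, and Ccl9 (-2.18), Fkbp11 (-2.03), a folding factor of the endoplasmic reticulum, and Nupr1 (-1.95) lowest. All 8 measured lipid absorption genes were higher (median 3.61), while the 3 MHC class II genes were lower (median -1.29; Cd74 -1.43). With the lipid absorption genes, genes of enterocytes and of cycling crypt cells were also higher, in 3 of 3 for digestive enzymes (median 2.24), 9 of 11 for the brush border cytoskeleton (1.71), 11 of 14 for S phase (1.27) and 7 of 12 for G2 and M phase (1.09). The doxycycline cells of cluster 17 had the same median Scrublet score as those of cluster 14, 0.0758. Of 9 measured antimicrobial genes, 4 were higher and 0 lower (median 0.45), led by Saa1 and Dmbt1, while the Paneth cell products Lyz1 (-0.26) and Ang4 (-0.60) did not pass the size rule. The median log2 ratio of genes above 10 CPM in both libraries was 0.53, and the 10 genes most counted in the control took 74.7% of its UMIs and 64.8% in the doxycycline library. Counted as CPM, 1588 of 4484 genes were higher and 86 lower (94.9% higher). Relative to the median they were 649 and 249 (72.3% higher). Without conditions on leading genes, cluster 15 joined the class, 547 genes were higher, and the log2 ratio was 0.00080 for Fabp1, -2.34 for Fabp2, -1.79 for Anpep and -0.74 for Apob. With every cell weighing the same, Anpep had -0.25 and 226 genes were lower.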

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

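The comparison of barcodes left out by the cell filter was chosen after the data were seen. It covers 13045 control and 4698 doxycycline barcodes that enter the report's comparisons only under other filters, most of them above the limit of 25% mitochondrial UMIs, and its values are CPM without mitochondrial genes. Each gene stood out because it was higher in the left-out barcodes of the doxycycline library than in those of the control. Pou5f1 was at 97.3 CPM in the left-out doxycycline barcodes and 2.00 in the left-out control barcodes, against 13.8 in the kept doxycycline cells. Sox2 was at 15.3 and 0.0528 CPM, against 2.17 in the kept doxycycline cells. Myc was at 65.4 and 13.3 CPM, against 22.9 in those kept cells. Ptgs1 was at 66.8 and 0.686 CPM, against 18.2 in them. Ptgs2 was at 1.03 CPM in the doxycycline and 0 in the control barcodes, against 0.899 in the kept doxycycline cells. Ly6a was at 67.3 and 2.80 CPM, against 112 in the kept doxycycline cells. Clu was at 19.7 CPM in the doxycycline and 0 in the control barcodes, against 17.5 in the kept doxycycline cells. The left-out doxycycline barcodes held 1320 Pou5f1 UMIs. The filter thus left out barcodes with higher Pou5f1, Sox2, Myc and Ptgs1 levels than the kept cells. The main values of these genes, also per cluster, hold for kept cells only.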

How the results depend on the processing

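The alternatives chosen only after the data were seen were the Scrublet score limit of 0.2, the enterocyte-like cells with at least 10000 UMIs, the goblet-like cluster 14 alone and naming without conditions on leading genes. No paired analysis was possible because each group has 1 library and no test was run. Among single genes 6835 values stayed within their counting interval, 2411 moved and 17 turned direction. Among the main results 236 stayed within it, or within 1.5 times for a count of genes, and 100 moved. The cause of a shift was not tested except where the alternative itself sets it, as for minimums on CPM and for depth. Keeping called doublets left both numbers of kept cells as they were within their intervals. Depth limits the control library, with a median of 4746 UMIs per kept cell against 24356.5 in the doxycycline library.

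Of cells with a UMI, thinning to 2500 UMIs, which left out 887 control cells and 206 doxycycline cells, gave 0.382% and 4.33% (control and doxycycline) for Pou5f1, 1.63% and 10.1% for Ly6a and 1.67% and 0.474% for Lgr5. Unthinned shares were 1.65% and 17.3%, 5.05% and 19.7% and 5.66% and 2.99%.

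Under the looser cell filter the log2 ratio was 3.88 for Pou5f1 and 0.71 for Myc, and 967 genes were higher in enterocyte-like cells. Shares in control and doxycycline cells were 37.8% and 42.0% enterocyte-like, 11.4% and 10.1% crypt-like and 8.67% and 2.29% goblet-like, and in the control 1.33% Paneth-like and 5.17% T cell or intraepithelial lymphocyte-like. Under the stricter filter Myc had 0.23, and shares were 19.7% and 49.7% enterocyte-like, 25.4% and 4.43% goblet-like, 4.29% and 2.28% Paneth-like, 13.3% crypt-like in the doxycycline and 15.9% T cell or intraepithelial lymphocyte-like in the control library. With called doublets kept, which added 2 cells, the clusters formed anew and enterocyte-like shares were 30.5% and 41.0%. With scores above 0.2 left out they were 31.1% and 40.9%, and goblet-like cells were 3.75% of the doxycycline cells. Over every deposited barcode the log2 ratios were 4.16 for Pou5f1, -0.24 for Klf4 and 0.96 for Myc.

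Median scaling gave -0.26 for Klf4 and 649 higher and 249 lower genes in Paneth-like cells. With every cell weighing the same, lower genes numbered 1433 over all kept cells, 2322 in enterocyte-like, 516 in crypt-like and 226 in Paneth-like cells, and goblet-like cells had 632 higher and 681 lower. Log2 ratios were then 4.32 for Pou5f1, -0.69 for Klf4 and 1.05 for Myc, and in Paneth-like cells Anpep turned to -0.25 and Tfcp2l1 to -0.058. Without a minimum on CPM, higher and lower genes were 1083 and 2990 over all kept cells, 1315 and 2409 in enterocyte-like, 595 and 970 in crypt-like, 763 and 859 in goblet-like and 3420 and 250 in Paneth-like cells, with 18 interferon response genes lower over all kept cells and 13 injury-associated genes higher in crypt-like cells. At 50 CPM they were 192 and 189, 290 and 563, 42 and 72, 91 and 138, and 351 and 22 in the same order. Injury-associated genes higher were then 7 over all kept cells, 6 in enterocyte-like and 1 in crypt-like cells, and interferon response genes lower 3 over all kept cells and 9 in enterocyte-like cells.

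At a Leiden resolution of 0.5, 319 genes were higher in enterocyte-like cells, where Dmbt1 turned to -0.021, Fbl to -0.63, Hk2 to -0.66 and Ptma to -0.48. Enterocyte-like cells were then 46.4% of the control, and crypt-like shares were 17.4% and 20.6%. At resolution 2, goblet-like cells had 726 higher and 680 lower genes and shares of 15.2% and 4.60%, and enterocyte-like cells were 42.8% of the doxycycline cells. Centring within each library gave 35.0% and 43.9% enterocyte-like cells and 3.88% goblet-like doxycycline cells. Allowing the response lists gave 38.5% and 44.5% enterocyte-like cells, 13.2% crypt-like doxycycline cells and 15.1% goblet-like control cells.

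Without conditions on leading genes 560 genes were higher in goblet-like and 547 in Paneth-like cells, goblet-like cells were 16.2% of the doxycycline and Paneth-like cells 7.60% of the control cells. In Paneth-like cells Anpep then turned to -1.79, Apob to -0.74, Ccl25 to -0.074, Fabp2 to -2.34 and Reg3b to -0.093. In enterocyte-like cells with at least 10000 UMIs, 735 genes were lower and Plk3 turned to 0.74. In the goblet-like cluster 14 alone, Aqp4 turned to -0.033, Ccnb1 to -0.037, Ggt1 to 2.09, Gsdmd to 1.55 and Ifit1 to 1.09.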

Other observations

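The lists of glucocorticoid targets and of stomach, stratified squamous, intestine, ileum, and duodenum and jejunum genes were written after the data were seen. The tests of surface cells of the stomach, of an epithelium outside the intestine, of doublets by response genes, of the OSKM factors in cluster 7, of free RNA, of Fkbp5 against Pou5f1 and of dissociation stress were chosen only after the results were seen.

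Several genes that respond to glucocorticoids were higher in the doxycycline library. Over all kept cells Fkbp5 was at 8.13 CPM in the control and 179 in the doxycycline library, the kinase gene Sgk1 at 16.9 and 202 and Zbtb16 at 0.0526 and 23.8. Of 7 measured targets picked after their values were seen, 6 were higher (median log2 2.28). Of 9 measured targets not yet looked at, 1 was higher, Per1 at 6.24 and 29.4 CPM (median 0.079). Of the 2 measured ileum genes (median -1.20), Fabp6 was lower, at 1206 CPM in the control and 121 in the doxycycline library, and Cyp2b10 was at 13.3 and 25.2. Within enterocyte-like cells, 1 of 3 measured ileum genes was lower by the size rule (median -0.98), with Fabp6 at 4124 and 247 CPM, Slc10a2 at 23.2 and 11.7 and Cyp2b10 at 89.1 and 56.3, and Fgf15, under 10 CPM, was at 6.49 and 0.338. The labels do not say whether the same parts of the small intestine were taken. None of the 2 measured duodenum and jejunum genes passed the size rule (median 0.56), 1 of 10 general intestine genes was higher (median 0.097), 1 stratified squamous gene was measured (Krt13, 7.27) and no stomach gene on the list was. Cluster 12 of the doxycycline library, led by Dmbt1, Cdca3, Edn1 and Fkbp5, had injury-associated genes below the other doxycycline cells, with 0 of 24 members higher and 14 lower (median log2 -1.33).

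Cluster 7 joined Ly6a, Ptgs1 and Clu with the stomach gene Gkn1 and with Krt14 (78.1 CPM) and Krt13 (192 CPM), keratins of stratified epithelia. Of the other stratified squamous genes listed, Krt5, Krt4 and Trp63 had 0 UMIs in it. Krt15 was at 0.459 against 1.55 CPM in the other doxycycline cells and Dsg3 at 4.31 against 0.355. Cdx1 was at 8.72 against 122 CPM in the other doxycycline cells. The tables argue against stomach cells carried in with the tissue, since the stomach genes not yet looked at (Tff2, Muc6, Pgc and others) summed to 0.367 CPM, and against its surface cells, since Tff1 and Muc5ac summed to 4.50 CPM, although Muc5ac (4.40 against 0.0507 CPM) and Gkn2 (795 against 3.97) were above the other doxycycline cells. They also argue against doublets of other kept cells as the source of the whole cluster, since a doublet lies between its parts and is rarer than they are. The genes compared were 132 response genes kept out of the clustering, without Ly6a, Ptgs1, Ptgs2, Clu and Pou5f1. In the cluster, 10 of them were at least 2 times as high as in any other cluster with at least 50 doxycycline cells. These 10 also had more UMIs in it than in all other kept doxycycline cells (Anxa1 4793 against 737, Cxcl5 788 against 130). The caller, which had not worked, gave a score 1.04 times that of the other cells, which decides nothing. Another epithelium from outside the intestine stays open, because general intestine genes went apart (median log2 -0.34). Cdh17 (0.16), Tspan8 (0.069), Lgals4 (0.051), Phgr1 (-0.14), Cldn7 (-0.19) and Muc13 (-0.50) lay near the other doxycycline cells. Tm4sf20 (-4.55), Isx (-2.07), Mep1a (-1.74) and Cldn15 (-1.43) lay below them. Expression of the cassette in cluster 7 stays open too. Against the other doxycycline cells Pou5f1 was at 5.82 times and Sox2 at 6.83 times, but Myc at 1.70 times and Klf4 at 0.503 times. The test asked for at least 2 times for each factor. Kept control cells already held Klf4 at 227 and Myc at 17.4 CPM without mitochondrial genes, against 1.26 for Pou5f1 and 0.0194 for Sox2. Cassette transcripts could be hidden at such levels, so the Klf4 and Myc ratios do not decide. High Pou5f1 was also among the features that singled the cluster out.

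MHC class II genes were lower in the doxycycline library in every class compared, and enterocyte-like cells with at least 10000 UMIs had a median log2 ratio of -5.18, which argues against lower depth of the control enterocyte-like cells. The tables argue against free RNA of cells like the 15 control cells of cluster 21, which would carry their other transcripts. Cd79a, Cd79b, Ms4a1, Tyrobp and Fcer1g per Cd74 UMI, relative to those cells, reached at most 0.0165 in any control class compared. Markers such as Lyz2, Csf1r and C1qa had 0 UMIs in cluster 21. Other antigen-presenting cells, such as macrophages, therefore had no source in this ratio and were not tested. Crypt-like doxycycline cells without a Pou5f1 UMI lay at -2.21 against the control, and those with one at -2.80. Doxycycline itself, or a change outside the epithelial cell, cannot be told apart from the cassette within it, because only the doxycycline library received the drug and a cell without a Pou5f1 UMI may still express the factor. A difference in the parts of the small intestine taken was not tested for MHC class II genes. The ileum gene Fabp6 was lower in enterocyte-like and also in crypt-like (-4.17), goblet-like (-3.38) and Paneth-like cells (-4.68).

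The glucocorticoid targets divided between those picked from the data and those not yet looked at, whose median log2 ratios were 0.42 in enterocyte-like, 0.46 in crypt-like, -0.16 in goblet-like and 0.95 in Paneth-like cells. The test of a state of the whole animal asked for a median of at least 1 in every class and took one under 0.5 in any class as evidence against. Medians in enterocyte-like, crypt-like and goblet-like cells lay under that bound. A further condition, that no target be higher, was added after the results were seen. Targets higher and lower were 3 and 2 of 10 in enterocyte-like, 2 and 0 of 8 in crypt-like and 2 and 1 of 9 in goblet-like cells. In goblet-like cells (quartiles -0.60 to 0.017) Per1 was at 2.28, Tsc22d3 at 1.04 and Rhob at -1.14. By the bound as first written the medians argue against that state, and by the later condition it stays open. Stress from dissociation is argued against in enterocyte-like, goblet-like and Paneth-like cells, where the median of the dissociation stress list was at most 0.12 and none of its measured genes was higher, and stays open in crypt-like cells, where the median was 0.56 and 2 of 17 were higher. Expression of the cassette within each cell stays open, since Fkbp5 was 0.678 times as high in cluster 7, where Pou5f1 was highest among clusters with at least 50 doxycycline cells, as in the other doxycycline cells, and 1.97 times as high in cluster 4, where Pou5f1 came next. A difference between the animals themselves was not tested.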
